A study of Mus musculus with 6 samples.

How the data were processed

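Messenger RNA libraries from colon epithelial cells of 6 untreated mice were compared, 3 labelled Ube2f_flox and 3 labelled Ube2f_dIEC. Per the labels, the mice were males of 8 weeks, cells were released from colon pieces with EDTA in buffered saline and strained, and RNA was taken up in Trizol. The series text describes oligo(dT) selection and paired-end sequencing. It does not say whether the libraries keep strand, so antisense and overlapping genes cannot be told apart. Each mouse is labelled as a separate animal.

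The deposited table gives a raw count and an FPKM value per gene and library. The counts are whole numbers, per the file headers and the values, and the FPKM values are scaled by gene length and library size, by the authors. Per the submitters' processing notes, cutadapt 1.9, HISAT2 2.2.1, StringTie 2.1.6, DESeq2 and edgeR were used with mm10. How the counts were derived from the alignments is not given in the sources used here. Of 26774 gene IDs found in GENCODE release M21 (GRCm38), 517 (1.93%) had exactly the coordinates listed in the table. Why the others differ, for example through another annotation or build, was not tested. Positions printed here are those of GENCODE M21 looked up by gene ID. Nuclear copies of mitochondrial genes carried counts close to those of the mitochondrial genes and made up 2.45 to 5.20% of each library. Reads with several matches give such counts if they are counted at each match, and also if each is placed at 1 match drawn at random, and no test here separates the 2. How such reads were counted in near-identical genes, such as the H2-T, H2-Q and Ces2 families, is equally unknown. Some annotation terms (1984 of the GO cells) were withheld in the table and did not enter the term test.

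All 6 libraries and all 28500 genes were read, and the table held 0 other columns of samples. Genes were kept by edgeR's filterByExpr with the genotype as group (17900 genes), scaled by TMM and tested with the edgeR quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3), 2-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The model held the genotype and no block. Replicate numbers are shared by the genotypes but the labels do not tie them to a litter or day. Standard errors are the log2 fold change divided by the square root of the F statistic. The biological coefficient of variation was 24.8%. DESeq2 1.42.0 was run as an alternative. Totals ran from 55971362 to 77524693 counts, so 3 counts, taken as the floor of detection, correspond to 0.0376 to 0.0529 CPM. Floors cover counting error only, and reads without molecular identifiers are not independent molecules. With 3 animals per genotype an exact permutation test of a single value cannot go below p = 0.1. Replicates of a genotype differed by far more than sampling noise (chi-square per degree of freedom of 25.3 to 177), so none were merged. Libraries did not group cleanly by genotype. Ube2f_flox replicate 1 correlated (log CPM) at 0.976 and 0.975 with Ube2f_dIEC replicates 2 and 3. With Ube2f_flox replicates 2 and 3 it correlated at 0.972 and 0.966. The 3 Ube2f_dIEC libraries correlated with each other at 0.973 to 0.981.

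Before the data were examined, 31 gene lists were fixed: neddylation and cullins, STAT5 pathway and targets, absorptive colonocyte, goblet, stem cell and Wnt, proliferation, enteroendocrine, tuft, antimicrobial and Paneth, junction and adhesion, NF-kB inflammatory, interferon response, MHC class II, p53 and apoptosis, NRF2, endoplasmic reticulum stress, lipid and PPAR, sterol synthesis, xenobiotic metabolism, immediate early and heat shock, circadian, B and plasma cell, T and innate lymphoid, myeloid, fibroblast and matrix, smooth muscle, endothelial, glial and neuronal, blood and fat, pancreas and small intestine, colon position, and sex genes. Some genes stand in more than 1 list, for example Retnlb. Lists were tested with limma's camera (preset correlation 0.01, Benjamini-Hochberg over the 31 lists), and again with an estimated correlation and with fry. Members were counted as passing over all genes and adjusted over the list alone.

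The rule for named genes was also fixed then. It takes Ube2f, Ptprn, Stat5a and Stat5b. It takes up to 10 genes per direction of largest log2 fold change among those past the threshold, with a mean of at least 1 CPM, a symbol and no overlap between the genotypes, passing over gene models (1 was passed over). Where fewer than 10 pass it adds, up to 5 in that direction, genes of smallest p, said not to pass. It takes up to 4 called members of each list, read here as called over the list alone, or with no call the 2 members of highest CPM. Members named beyond this rule, and Mt2, were chosen after their values were seen. Some genes that the rule or the tables give are not reported here. The term test was set to run only with at least 20 called genes in a direction, so it was not run on the 8 called genes.

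The tests were checked on 3 simulated data sets of this comparison with 200 changed genes each. Of genes with a simulated log2 fold change of 1 edgeR called 54.1%, of those with 2 it called 74.8%, and of unchanged genes 0.0566%. DESeq2 called 66.9%, 81.3% and 0.273%. A list with a simulated log2 fold change of 0.5 was called in 3 of 3 sets by camera, by camera with an estimated correlation and by fry, and 0 other lists were called. Genes were simulated independently, so these sets cannot show how often camera calls lists whose members vary together. In the data the estimated correlation ran from -0.081 (pancreas and small intestine) to 0.848 (T and innate lymphoid), and was 0.41 for the sterol list.

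Alternatives fixed beforehand were other normalizations (RLE, upper quartile, library totals), no filter and a stricter filter (10 counts in 3 libraries and a mean of 1 CPM), DESeq2, limma-voom, a replicate block, each library left out, a minimum log2 fold change of 1, an unadjusted p, and limma-trend on log2(FPKM + 1) or log2(FPKM + 0.1) for genes with a mean FPKM of at least 1. Chosen after seeing the data were leaving out X and Y genes, leaving out mitochondrial genes with their nuclear copies, DESeq2 without each library, and the list counts under each alternative. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.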

Results

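Messenger RNA was sequenced from colon epithelial cells of untreated mice, 3 Ube2f_flox mice and 3 Ube2f_dIEC mice, labelled as males of 8 weeks. Ube2f encodes an E2 enzyme that passes NEDD8, a ubiquitin-like protein, to cullin proteins. The labels call the Ube2f_flox animals wild type, and dIEC stands for the labels' deletion in intestinal epithelial cells. The cells had been released from the opened colon with EDTA, so other cells of the mucosa could be present. Total counts per library were 77524693, 71240407 and 63247380 for Ube2f_flox replicates 1 to 3 and 55971362, 72422108 and 76483134 for Ube2f_dIEC replicates 1 to 3. Levels are given as CPM, counts scaled to library size with TMM factors, as mean ± SD of 3 libraries per genotype, and log2 fold changes are Ube2f_dIEC over Ube2f_flox with their standard error (SE).

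The comparison asks how the transcriptome of the unchallenged colon differs between mice with and without the deletion of Ube2f in the epithelium. No other control group was sequenced. The loss of Ube2f thus cannot be told apart from other differences between the sets of mice, such as the means of deletion or the breeding of the lines. The deleted gene itself (ENSMUSG00000034343; GRCm38 chromosome 1, 91250304 to 91290337) was at 36.1 ± 5.29 CPM in Ube2f_flox and 18.7 ± 2.02 CPM in Ube2f_dIEC, a log2 fold change of -0.95 (SE 0.13), and each Ube2f_dIEC library lay below each Ube2f_flox library. Over all 17900 genes tested this did not pass the 0.05 threshold (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0923). Adjusted over the list alone, Ube2f was the 1 gene of 26 in the neddylation and cullin list that fell. DESeq2 gave the same log2 fold change with an adjusted p of 1.09e-07, and edgeR without Ube2f_flox replicate 1 gave an adjusted p of 0.0461. The labels do not say which exons were removed, and reads from the remaining exons and from cells outside the epithelium count toward these values. The series title names PTPRN and phosphorylated STAT5. Ptprn, a member of the receptor-type tyrosine phosphatase family found in secretory granules, was at 1.08 ± 0.453 CPM against 1.01 ± 0.291 CPM (log2 fold change -0.10, SE 0.43; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.972). Stat5a (-0.18, SE 0.11) and Stat5b (-0.07, SE 0.11) did not pass either, and phosphorylation is not measured by RNA.

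The STAT5 list, which holds the pathway's kinases, receptors and known target genes, moved in both directions. Of 23 measured members, 2 rose and 1 fell when adjusted over the list alone, and 0 passed over all genes. Socs2 rose from 21.4 ± 0.729 to 41.8 ± 6.89 CPM (log2 fold change 0.97, SE 0.12) and Cish from 27.9 ± 3.61 to 51.2 ± 8.15 CPM (0.88, SE 0.14). Both are feedback inhibitors of cytokine signalling that STAT5 induces. Bcl6, a transcriptional repressor that STAT5 represses, fell from 12.98 ± 2.54 to 5.51 ± 1.26 CPM (-1.23, SE 0.22). The other 20 members did not pass, among them Ccnd1 (0.41, SE 0.13) and Ccnd2 (0.38, SE 0.12), and the list as a whole was not called (median log2 fold change -0.10, or 0.06 with library totals alone; camera adjusted p = 0.614). Camera looks for a shared direction, which a list of kinases, receptors and both induced and repressed targets need not have. Without Ube2f_flox replicate 1, 4 members rose and 5 fell over the list alone, and without Ube2f_dIEC replicate 2, 2 rose and 3 fell.

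**Figure D1:**
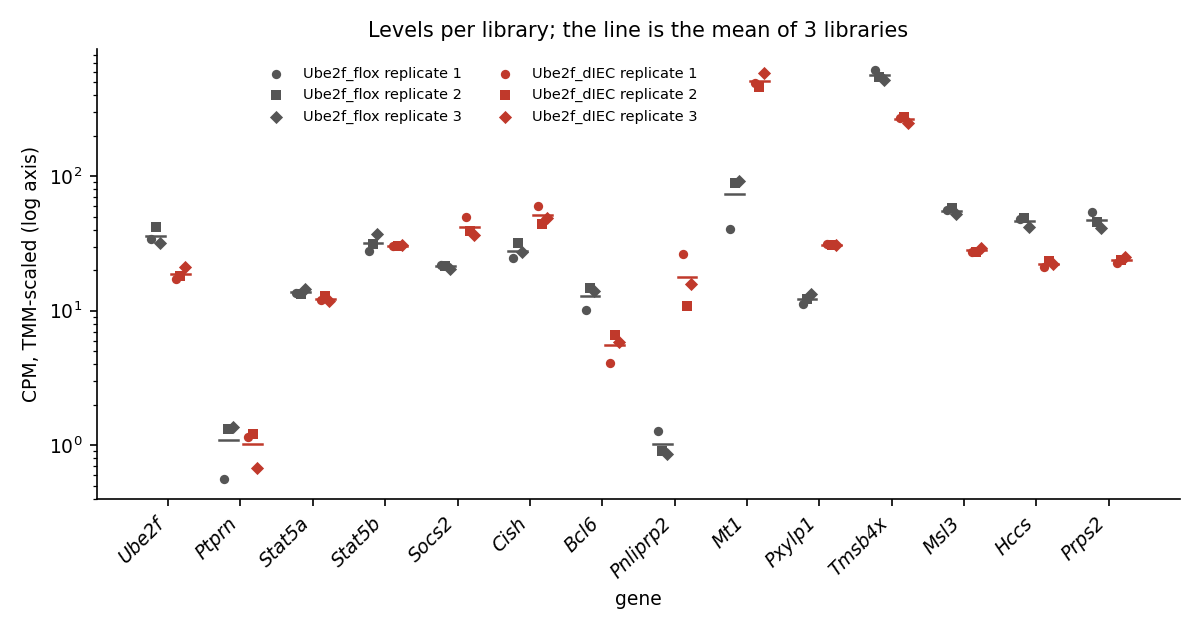
CPM of 14 genes in each library on a log axis, with grey marks for Ube2f_flox, red marks for Ube2f_dIEC, marker shape for the replicate number and a line at the mean of 3 libraries. Ube2f lay lower in each Ube2f_dIEC library than in each Ube2f_flox library, while the Ptprn libraries of both genotypes overlapped.

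Over all genes, 8 of 17900 passed, 4 higher and 4 lower in Ube2f_dIEC. Pnliprp2, a pancreatic lipase-related protein, rose from 1.02 ± 0.230 to 17.7 ± 8.06 CPM (log2 fold change 4.11, SE 0.36; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0107). Mt1, a metal-binding metallothionein, rose from 74.0 ± 28.8 to 515 ± 63.0 CPM (2.80, SE 0.29; adjusted p = 0.0268 in the same edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Its neighbour Mt2 was at 34.4 ± 17.5 against 38.5 ± 13.8 CPM (0.16, SE 0.42). Pxylp1, a xylose phosphatase of glycosaminoglycan synthesis, rose from 12.3 ± 1.08 to 31.0 ± 0.477 CPM (1.33, SE 0.10). The remaining gene that rose, the gene model Gm18736, lay outside the naming rule. Gatm, an enzyme of creatine synthesis, was at 3.39 ± 0.966 against 25.0 ± 10.7 CPM (2.88, SE 0.35) and missed the threshold at an adjusted p of 0.0591 (edgeR quasi-likelihood, Benjamini-Hochberg).

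The 4 genes that fell lie near each other at the distal end of the X chromosome, with Tlr8 (0.61, SE 0.57) and Tlr7 (-1.36, SE 1.63), both under 1 CPM, and Arhgap6 (-0.89, SE 0.32) among the genes between them. Tmsb4x, which encodes the actin-binding peptide thymosin beta 4, fell from 566 ± 49.7 to 266 ± 12.95 CPM (log2 fold change -1.09, SE 0.09). Hccs, the holocytochrome c synthase, fell from 46.2 ± 3.87 to 22.2 ± 1.13 CPM (-1.06, SE 0.09). Msl3, a chromatin protein of the MSL complex, fell from 55.6 ± 2.98 to 28.1 ± 1.07 CPM (-0.98, SE 0.08). Prps2, a phosphoribosyl pyrophosphate synthetase, fell from 47.0 ± 6.48 to 23.9 ± 1.202 CPM (-0.98, SE 0.11; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0455). Within GRCm38 X, 167207093 to 170005736, 6 genes had at least 1 CPM, and their log2 fold changes ran from -1.09 to -0.65. The 22 genes of that level in the 5 Mb before it had a median of 0.13, and 0 of them passed. Outside the X run, the class I-like gene H2-T26 was at 11.1 ± 3.32 against 2.40 ± 0.523 CPM (-2.20, SE 0.27), with an adjusted p of 0.0619 (edgeR quasi-likelihood, Benjamini-Hochberg).

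**Figure D2:**
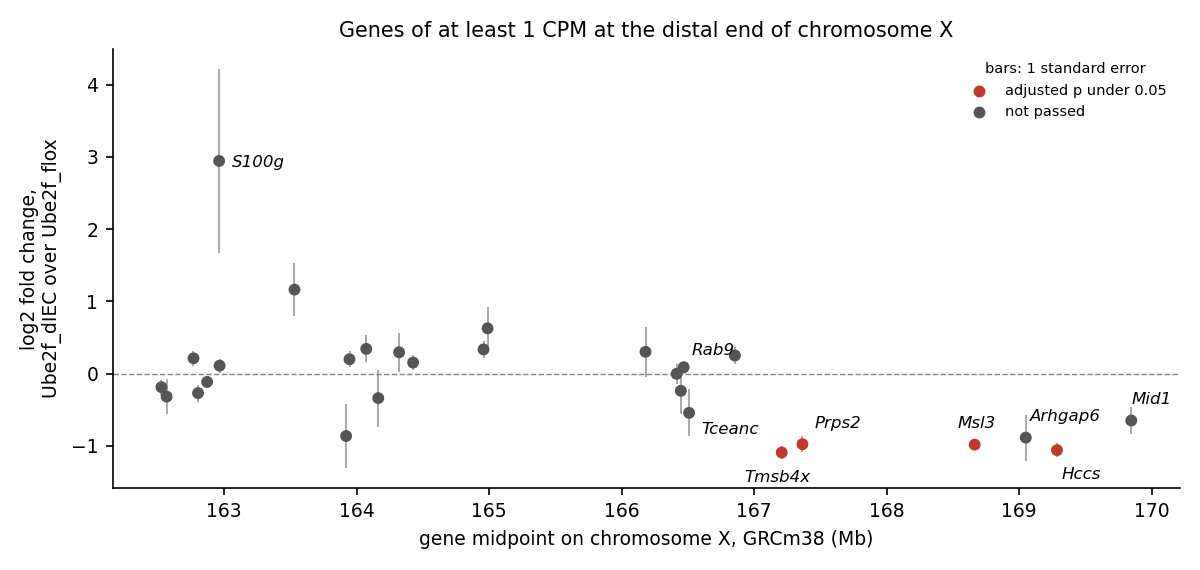
Log2 fold change with 1 SE against the gene midpoint (Mb, GRCm38) for genes of at least 1 CPM at the distal end of chromosome X; red marks passed at an adjusted p under 0.05. Tmsb4x, Prps2, Msl3, Arhgap6, Hccs and Mid1 lay between -1.09 and -0.65, and the genes before them had a median of 0.13.

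The count of 8 moved with the test and with single libraries. DESeq2 called 234 genes (111 higher, 123 lower), the 8 included, limma-voom called 5, and library totals in place of TMM gave 18 (13 higher, 5 lower). In the simulated sets DESeq2 had a larger share of false calls than edgeR. Ube2f_dIEC replicate 1, labelled male, carried 494 CPM of Xist, the RNA of the inactive X, against at most 1.33 CPM in the other 5 libraries. It had 0 counts of the Y-linked Ddx3y, Eif2s3y, Kdm5d and Uty, where 3 counts correspond to 0.0503 CPM. Without it edgeR called 0 genes over all genes, with 1129 at an unadjusted p under 0.05 and 167 by DESeq2. Leaving out Ube2f_flox replicate 2 or Ube2f_dIEC replicate 3 also gave 0 (1240 and 1127 at an unadjusted p under 0.05; 205 and 166 by DESeq2), Ube2f_dIEC replicate 2 gave 1, and Ube2f_flox replicate 1 gave 90.

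Genes of cholesterol synthesis were higher in Ube2f_dIEC. Of the 20 members of the sterol list, 13 rose and 0 fell when adjusted over the list alone, 0 passed over all genes, and 19 had a positive log2 fold change (median 0.43). Hmgcs1, an enzyme early in the pathway, rose from 173 ± 6.52 to 249 ± 24.7 CPM (0.53, SE 0.09). Lss, which acts late in it, rose by 0.52 (SE 0.08) on the log2 scale, and Fdft1, squalene synthase, by 0.57 (SE 0.10). The list was called by camera (Benjamini-Hochberg adjusted p = 3.69e-16 with a preset correlation of 0.01), with an adjusted p = 0.280 with an estimated correlation. Without Ube2f_dIEC replicate 1, 10 of the 20 rose when adjusted over the list alone.

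All 28 proliferation genes had positive log2 fold changes (median 0.50). Adjusted over the list alone 6 rose, namely Mcm3, Mcm4, Mcm5 and Mcm6 of the replicative helicase, the S-phase transcription factor E2f1 and the ribonucleotide reductase subunit Rrm2, and 0 passed over all genes. Mcm4 went from 27.6 ± 5.23 to 41.9 ± 2.95 CPM (0.60, SE 0.14) and Rrm2 from 19.2 ± 4.73 to 33.1 ± 7.13 CPM (0.79, SE 0.21). The list was called by camera (adjusted p = 1.54e-11), with an adjusted p = 0.547 with an estimated correlation. The number of members passing changed with the library left out, though each leave-out also has less power. It was 0 without Ube2f_flox replicate 2 or 3 or Ube2f_dIEC replicate 2 or 3. It was 25 without Ube2f_flox replicate 1 and 5 without Ube2f_dIEC replicate 1. Mean levels of the list were lower in Ube2f_flox replicates 2 and 3 (-0.42 and -0.63 on the log2 scale around the mean of the 6 libraries) than in Ube2f_flox replicate 1 (0.28). They were 0.45, 0.36 and -0.05 in Ube2f_dIEC replicates 1 to 3, so that Ube2f_dIEC replicate 3 lay below Ube2f_flox replicate 1.

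Among the epithelial lineages, goblet cell genes were higher. Of 20 members, 10 rose and 1 fell adjusted over the list alone, and 0 passed over all genes (median 0.20; camera adjusted p = 2.45e-06, and adjusted p = 0.280 with an estimated correlation). Clca1, a secreted mucus protein, went from 749 ± 458 to 3161 ± 942 CPM (2.08, SE 0.47). Retnlb, an antimicrobial resistin-like protein, went from 97.8 ± 35.1 to 305 ± 58.2 CPM (1.64, SE 0.25). Muc2, the main gel-forming mucin of the colon, went from 6865 ± 219 to 9067 ± 1044 CPM (0.40, SE 0.11), and the lineage factor Atoh1 rose by 0.31 (SE 0.08). The 9 members that did not pass included Spdef (-0.14, SE 0.22), Foxa3 (-0.01, SE 0.13) and Creb3l1 (0.03, SE 0.115). Tff3, a trefoil peptide of the same cells, fell (-0.33, SE 0.09). Without Ube2f_dIEC replicate 1, 5 rose and 0 fell, and 5 to 7 rose without Ube2f_flox replicate 2 or 3 or Ube2f_dIEC replicate 2 or 3.

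The antimicrobial and Paneth list split. Of 23 members 4 rose and 3 fell adjusted over the list alone, and 0 passed over all genes. Retnlb was joined by the lectin Itln1 (2.28, SE 0.40), the pentraxin Mptx1, from 349 ± 232 to 1851 ± 547 CPM (2.41, SE 0.51), and the phospholipase Pla2g2a (1.84, SE 0.43). The acute-phase proteins Saa1 (-1.35, SE 0.32) and Saa3 (-0.88, SE 0.23) and the oxidase maturation factor Duoxa2 (-0.89, SE 0.23) fell. The list was not called (camera adjusted p = 0.755), and its median (-0.10, or 0.05 with library totals alone) and its camera direction differed in sign. Without Ube2f_flox replicate 2 or 3, 1 member fell, and without Ube2f_dIEC replicate 3, 7 rose.

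Markers of the other epithelial lineages were lower as lists, with few members past a test of their own. In the absorptive colonocyte list 21 of 23 log2 fold changes were negative (median -0.25), yet 0 members passed, with Car4 at 356 ± 74.8 against 238 ± 19.9 CPM (-0.58, SE 0.15) and the water channel Aqp8 at -0.75 (SE 0.24). In the enteroendocrine list 30 of 32 were negative (median -0.65). Adjusted over the list alone the hormone gene Sst fell (-2.42, SE 0.56), while Reg4, also a marker of deep crypt secretory cells, rose from 480 ± 38.3 to 698 ± 27.7 CPM (0.54, SE 0.09). Gcg, at 30.4 ± 14.4 against 13.3 ± 4.30 CPM, and Chga, at 37.6 ± 15.3 against 22.7 ± 4.35 CPM, did not pass. Of 20 tuft cell genes 19 were negative (median -0.48) and 0 passed. Camera called the absorptive (adjusted p = 3.83e-07), enteroendocrine (7.16e-05) and tuft (2.47e-05) lists, with an adjusted p = 0.280, 0.734 and 0.387 with an estimated correlation. The Sst call was absent without Ube2f_flox replicate 2 or 3 or Ube2f_dIEC replicate 3, and without Ube2f_flox replicate 1, 9 enteroendocrine and 6 absorptive members fell over the list alone. The enteroendocrine level was highest in Ube2f_flox replicate 3 (0.96 on the log2 scale around the mean of the 6 libraries), while Ube2f_flox replicate 1 (-0.10) lay below Ube2f_dIEC replicate 2 (-0.07), and without Ube2f_flox replicate 3 the camera adjusted p was 0.0364.

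MHC class II genes, which present antigen on myeloid cells, B cells and some epithelial cells, were lower. Of 10 members 5 fell and 0 rose adjusted over the list alone, and 0 passed over all genes (median -0.89). The invariant chain Cd74 went from 105 ± 35.7 to 35.4 ± 12.5 CPM (-1.57, SE 0.31) and H2-Ab1 from 33.8 ± 13.3 to 14.6 ± 3.81 CPM (-1.21, SE 0.31). Camera called the list (adjusted p = 0.000139), with an adjusted p = 0.547 with an estimated correlation. Without Ube2f_flox replicate 2, Ube2f_dIEC replicate 1 or Ube2f_dIEC replicate 2, 1 member fell, without Ube2f_flox replicate 3, 3 fell, and without Ube2f_flox replicate 1, 8 fell. List levels were -0.36, 0.65 and 0.78 in Ube2f_flox and -0.52, -0.58 and 0.04 in Ube2f_dIEC replicates 1 to 3 (log2 around the mean of the 6 libraries), so Ube2f_flox replicate 1 lay below Ube2f_dIEC replicate 3. Of the leukocyte lists, all 22 T and innate lymphoid genes (median -0.65) and 16 of 20 myeloid genes (median -0.70) had negative log2 fold changes, 0 members of either passed, and camera called both (adjusted p = 0.00624 and 0.00768, with an adjusted p = 0.857 and 0.734 with an estimated correlation). The B and plasma cell list was not called (median -0.23, camera direction up, adjusted p = 0.846). The level of the T cell list was highest in Ube2f_flox replicate 3 (1.23 above the mean of the 6 libraries on the log2 scale) and lowest in Ube2f_flox replicate 1 (-0.67), and the myeloid level of Ube2f_flox replicate 1 (-0.29) lay below that of Ube2f_dIEC replicate 2 (-0.13). Without Ube2f_flox replicate 3 neither leukocyte list was called (camera adjusted p = 0.996 for T and innate lymphoid and 0.221 for myeloid genes). The class II list was still called lower in that leave-out (camera adjusted p = 0.000945).

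**Figure D3:**
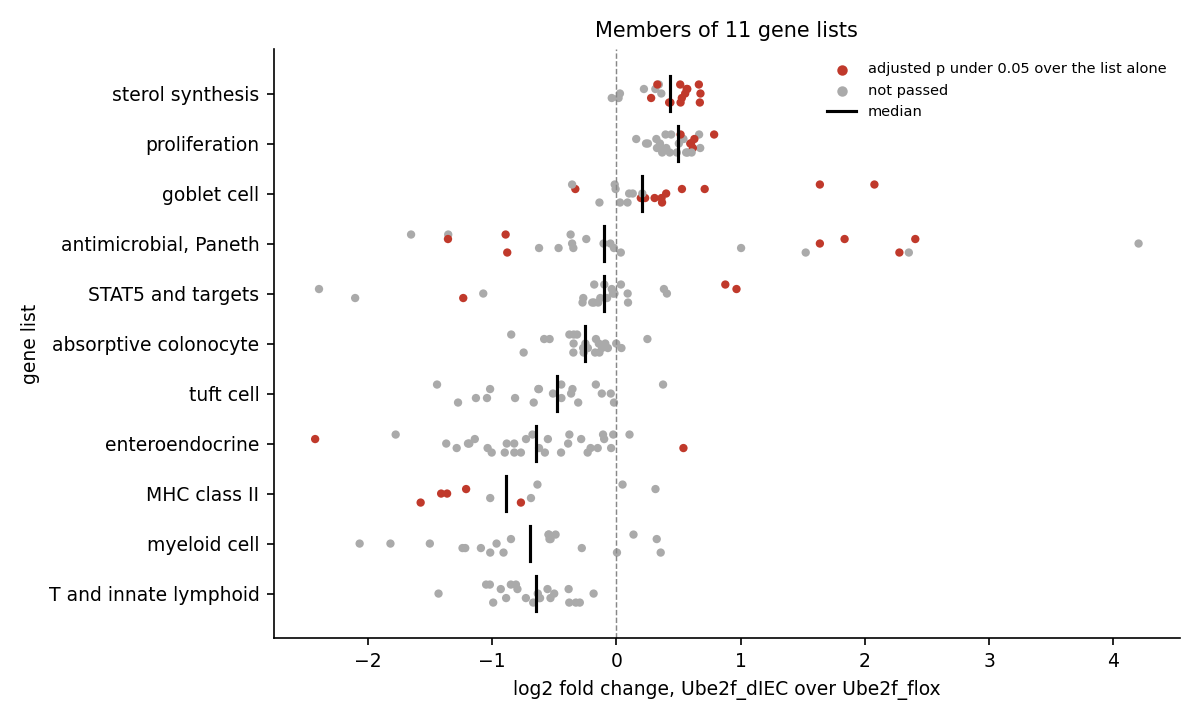
Log2 fold change of each measured member of 11 gene lists, with red marks for members of adjusted p under 0.05 over the list alone and a black line at the list median. In the sterol list 13 of 20 members passed, all above 0, and in the MHC class II list 5 of 10, all below 0.

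Camera called 14 of 31 lists in all, 4 higher and 10 lower, and 0 with an estimated correlation (15 and 5 lists at an unadjusted p under 0.05; 0 by fry, also 5). The remaining called lists were endoplasmic reticulum stress (higher, median 0.07, or 0.23 with library totals alone, with Asns the 1 member that rose), xenobiotic metabolism (lower, median -0.11, or 0.05 with library totals alone, with Cyp4f14, Sult1b1 and Ces2a falling), junctions and adhesion (lower, median -0.08, or 0.08 with library totals alone), interferon response (lower, median -0.19, or -0.03 with library totals alone) and blood and fat (lower, median -0.79, or -0.62 with library totals alone), the last 3 with 0 members passing. With an estimated correlation their adjusted p was 0.734, 0.280, 0.734, 0.857 and 0.290. The endoplasmic reticulum stress and interferon calls ended without Ube2f_flox replicate 3, Ube2f_dIEC replicate 2 or Ube2f_dIEC replicate 3, the former also without Ube2f_flox replicate 1 and the latter without Ube2f_flox replicate 2, where its camera direction turned to higher (adjusted p = 0.356). The junction call ended without Ube2f_flox replicate 2 or Ube2f_dIEC replicate 1, and the xenobiotic call without Ube2f_flox replicate 1. Without Ube2f_dIEC replicate 1 the blood and fat median was -1.52 and 5 of 7 members fell over the list alone (4 by DESeq2), and the interferon median was -0.31.

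The other 17 lists, neddylation, STAT5 and antimicrobial genes among them, were not called. Adjusted over the list alone, 1 member fell in the stem cell and Wnt (Smoc2, -0.58), immediate early and heat shock (Klf2, -0.61), circadian (Dbp, -0.58) and pancreas and small intestine (Rbp2, -1.22) lists. In the p53 and apoptosis list Tnfrsf10b rose (0.49), in the lipid and PPAR list Acsl1 (0.67) and Ehhadh (0.37) rose, and in the fibroblast and matrix list Fn1 rose (3.10, with 15.7 CPM in Ube2f_dIEC replicate 1 and 2.05 and 3.41 CPM in replicates 2 and 3). In the NF-kB inflammatory, NRF2, B and plasma cell, smooth muscle, endothelial, glial and neuronal, colon position and sex gene lists 0 members passed. The B cell median (-0.23) and its camera direction differed in sign, as did those of the neddylation list (0.01). Some of these lists were called with a library left out, the NF-kB (lower) and NRF2 (higher) lists without Ube2f_flox replicate 1, B cell genes (higher) without Ube2f_flox replicate 3, circadian, immediate early and p53 genes (lower) without Ube2f_dIEC replicate 3, and sex genes (lower) without Ube2f_dIEC replicate 2 or 3.

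Mitochondrial genes took 16.9 ± 4.01% of the counts in Ube2f_flox and 10.9 ± 0.450% in Ube2f_dIEC (2-sided exact permutation test, p = 0.1, the smallest p that 3 against 3 libraries allow). All 13 mitochondrial mRNAs had negative log2 fold changes, from -0.91 to -0.56, and 0 passed with edgeR, while DESeq2 called 11 of them lower. Leaving out mitochondrial genes and their nuclear copies before normalization gave 8 calls, the same 8 genes.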

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

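Leaving out X and Y genes or mitochondrial genes, DESeq2 without single libraries, and member counts of lists under the alternatives were chosen after seeing the data. The count of 8 genes stayed within 1.5 times under RLE (8) and upper-quartile scaling (8), no filter (7), the stricter filter (8), without mitochondrial genes (8) and with a log2 fold change of at least 1 (6). It was 18 with library totals, 234 with DESeq2, 5 with limma-voom, 4 with FPKM and either pseudocount (4 and 4), 4 without X and Y genes and 1464 at an unadjusted p under 0.05. Without X and Y genes the 4 that fell were not tested, which is by construction; the cause of the other differences was not tested. Library totals moved the median of all genes by 0.15 and FPKM by 0.14 and 0.17. Relative to that shift the sterol median was 0.43, proliferation 0.48, goblet 0.20, absorptive -0.25 and class II -0.88.

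Leaving out Ube2f_flox replicates 1 to 3 in turn gave 90, 0 and 6 genes with edgeR (3054, 1240 and 1048 at an unadjusted p under 0.05) and 1197, 205 and 162 with DESeq2. Leaving out Ube2f_dIEC replicates 1 to 3 gave 0, 1 and 0 with edgeR (1129, 1145 and 1127 at an unadjusted p under 0.05) and 167, 156 and 166 with DESeq2, against 8 and 234 with all libraries. Of the 14 called lists, 8 were called in all 6 leave-outs, which gave 11 to 16 called lists, and the count was 0 with an estimated correlation and 0 with fry (5 lists each at an unadjusted p under 0.05).

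Whether the numbers shared by the genotypes pair the libraries stays open. Deviations of same-numbered libraries correlated at 0.081, -0.015 and 0.083, under the bound of 0.1 set for pairing. Those of differently numbered libraries correlated at -0.109 to 0.037. With 3 libraries per genotype these values cannot decide the question. With a replicate block 10 genes passed, 6 of them among the 8, and 13 lists were called; in the proliferation list 22 members rose over the list alone, against 6.

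Over the named genes and alternatives 676 values kept their direction and side of the threshold, 43 lost the call, 53 gained it and 8 changed sign. The 8 belong to genes that did not pass anywhere. Stat5b was at 0.087 with library totals, at 0.081 and 0.095 with FPKM and from -0.169 (without Ube2f_flox replicate 1) to 0.036 (without Ube2f_flox replicate 3) in the leave-outs. Ptprn was at 0.073 with library totals and from -0.416 (without Ube2f_flox replicate 1) to 0.125 (without Ube2f_dIEC replicate 3) in the leave-outs. Ube2f kept a log2 fold change between -1.04 and -0.57 with adjusted p from 1.09e-07 to 0.320 over the edgeR, limma and DESeq2 alternatives. Prps2 lost its call under 11 of them, Tmsb4x, Msl3 and Hccs under 6, Pnliprp2 and Mt1 under 5 and Pxylp1 under 4. The term test had no main value and so no alternative to set against it. Genes under 1 CPM, such as Sst in Ube2f_dIEC, rest on few counts.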

Other observations

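In this part the 10 splits of the libraries and the random placements on chromosomes were planned before their results were seen, and all other tests were chosen afterwards. Beyond the fixed lists, the genes with an unadjusted p under 0.01 were tested for annotation terms. Among the higher genes, cholesterol biosynthesis held 9 of 26 annotated genes where 0.320 were expected by chance (hypergeometric test, Benjamini-Hochberg adjusted p = 3.00e-08), and DNA replication held 11 of 96 (1.18 expected, adjusted p = 1.84e-05), with Lig1, Pole, Pold1 and Cdc45 beside the Mcm genes. Among the lower genes, antigen processing and presentation held 12 of 68 (0.986 expected, adjusted p = 2.52e-08), with Ctss, Ctsl, H2-K1 and 4 H2-T genes beside the class II genes, and oxidative phosphorylation held 14 of 123 (1.78 expected, adjusted p = 1.42e-07), 13 of them mitochondrial transcripts. With the genes called by DESeq2, cholesterol biosynthesis held 8 (adjusted p = 1.02e-08), DNA replication 7 (adjusted p = 0.00106), oxidative phosphorylation 11, all mitochondrial (adjusted p = 1.18e-06), and antigen processing 9 (adjusted p = 1.18e-06). Those 9 held Cd74 but not H2-Aa, H2-Ab1 or H2-Eb1, whose DESeq2 adjusted p was 0.317, 0.118 and 0.218. Genes of a term are not independent, which the hypergeometric test does not allow for, so its p-values overstate the evidence. The estimated correlation was 0.41 in the sterol, 0.612 in the proliferation and 0.516 in the MHC class II list. The mitochondrial mRNAs come from 1 genome that took a larger share of counts in Ube2f_flox. The terms also share genes with the fixed lists and rest on the same libraries, so they are not separate support for those lists.

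Other genes chosen after their values were seen did not pass over all genes with edgeR quasi-likelihood and Benjamini-Hochberg adjustment. Clps, the cofactor of pancreatic lipase, was at 2.88 ± 0.879 against 9.12 ± 2.42 CPM (log2 fold change 1.66, SE 0.29), beside the rise of Pnliprp2. The receptor kinase Ros1 was at 0.267 ± 0.0820 against 4.51 ± 3.51 CPM and the scaffold Shank1 at 0.216 ± 0.131 against 4.56 ± 3.08 CPM. The class I heavy chain H2-K1 (-0.46, SE 0.13) and its partner B2m (-0.53, SE 0.16) were lower. On GRCm38 chromosome 8 the neighbouring carboxylesterase genes Ces2a (-0.79), Ces2c (-0.28), Ces2d-ps (-0.85) and Ces2e (-0.31) each had an unadjusted p under 0.01. On chromosome 9, between 104288251 and 105412229, Acp3 (1.04), Mrpl3 (0.59) and Aste1 (0.88) did. The Paneth cell lysozyme Lyz1 reached 8.92 CPM in Ube2f_dIEC replicate 2 and 0.218 and 0.351 CPM in replicates 1 and 3, and S100g reached 75.4 CPM in Ube2f_dIEC replicate 1 against 0.954 and 6.84 CPM in replicates 2 and 3.

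The real grouping of the 6 libraries called 8 genes, and the highest of the other splits called 1. For lists it called 14, and the highest of the other splits called 15. With 10 splits no share under 0.05 can be had. Of them 1, the real one, reached the real count of genes, so the splits settle nothing about chance for that count. For lists 3 of the 10 reached the real count, the real split among them. The number of lists called by camera was thus no higher than groupings that mix the genotypes can give.

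The lower genes at the distal X end were present in each Ube2f_dIEC library. The library with female transcripts does not account for them, because without Ube2f_dIEC replicate 1 the median log2 fold change of the 6 expressed genes was -0.99. Random placement of the 364 genes with p under 0.01 gave a permutation p of 2e-04 for 5 of 10 neighbours in 1 direction (10000 placements, with 1 added to both counts). A difference in copy number or cis regulation of the segment between the 2 sets of mice stays open. The genes with p under 0.01 define the run. The 6 other tested genes of the segment had a median of -0.35, between the bounds set for either answer. Of these, 3 were positive (Tlr8 0.61, G530011O06Rikx 0.28, Gm15726 0.18) and 3 negative (Tlr7 -1.36, BC022960 -0.89, Arhgap6 -0.89). That median cannot decide the question, since 5 of the 6 were under 1 CPM, with SE from 0.405 to 1.63. Arhgap6, at 1.99 CPM, had an SE of 0.32. Next to the segment Erdr1x was at -1.45 (SE 0.37). No sequence was analysed here, and a link to the Ube2f deletion on chromosome 1 or to the breeding of the lines stays untested.

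Of 9 tested H2-T genes on chromosome 17, 4 were lower and 2 higher at an unadjusted p under 0.01, with H2-T23 at 304 against 115 CPM and H2-T10 at 2.42 against 7.43 CPM. Reads moving between near-identical H2-T genes would leave the family total in place. The summed CPM was 440 ± 92.0 in Ube2f_flox and 202 ± 6.10 in Ube2f_dIEC (log2 ratio -1.12). Most of that total was H2-T23, so it says little about the smaller members, and shifts of a few CPM into H2-T10 or H2-T27 stay open. Reads placed in H2-Q or other genes outside the sum stay open as well. A weaker interferon response was not tested for the higher genes. For the lower genes it cannot be told apart, since with TMM scaling the interferon list had a median of -0.19, between the bounds set for either answer. With library totals alone it was -0.03, past the bound against a weaker response, but relative to the shift of all genes under that scaling it was -0.18. Without Ube2f_flox replicate 2 the camera direction of the list turned to higher (adjusted p = 0.356). Without Ube2f_flox replicate 1 or Ube2f_dIEC replicate 1 camera called the list lower (adjusted p = 8.51e-13 and 5.94e-05). In the remaining leave-outs its direction was lower and it was not called. List levels were -0.52, 0.55 and 0.17 in Ube2f_flox and 0.14, -0.20 and -0.14 in Ube2f_dIEC (log2 around the mean of the 6 libraries). A strain difference in the MHC region was not tested for these genes.

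A variant of the MHC region alone does not account for the whole set of lower MHC class II transcripts, because Cd74, on chromosome 18, was at -1.57 (SE 0.31). For H2-Aa, H2-Ab1 and H2-Eb1, which lie on chromosome 17, such a variant stays open. Fewer leukocytes in the Ube2f_dIEC preparations may account for the lower class II transcripts. The class II median (-0.89, 10 genes) lay below that of 56 pooled T cell, myeloid and B cell markers (-0.62), with a 2-sided permutation p of 0.182 over genes, which are not independent replicates. Lower expression in the epithelium itself, the biological alternative in the design, and fewer leukocytes therefore cannot be told apart with these libraries. Without Ube2f_flox replicate 3 camera called the class II list (adjusted p = 0.000945) but neither the T and innate lymphoid nor the myeloid list. That difference was seen in 1 leave-out only. Of the markers compared, Cd14 was at 23.2 against 25.5 CPM (0.14, SE 0.10), Ly6g at 16.1 against 11.1 CPM and Lck at 13.9 against 8.96 CPM. Cd14 was 1 of 4 myeloid genes with a positive log2 fold change, against 16 negative ones. All 22 T and innate lymphoid genes were negative. The cell strainer of the preparation would not hold back single leukocytes.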
